A study of Mus musculus with 4 samples.

How the data were processed

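Gene expression was measured in skin of mouse embryos at E17.5 on 4 Affymetrix whole-transcript arrays: 2 of control skin and 2 of skin with Ovol2 overexpression in the epidermis (Ovol2 BT). Per the labels' protocols, each array holds RNA of 2 mice, extracted with Trizol and column purification, amplified from random primers and labelled with biotin. Groups and replicate numbers were taken from the sample titles, which call the arrays biological replicates. No label states that arrays of the same number share a litter, day or batch, and no scan date was used here.

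The deposited values are linear intensities per probe set, made with Affymetrix Expression Console 1.1.1 and PLIER 2.0, per the submitters' processing notes. The background correction and the normalization between arrays within PLIER are not given in the sources used here. Nor is a genome build, so no coordinates are given. The values contain no detection calls, and about 10% of those on each array lie below 16 (9.98% and 10.1% in the controls, 10.00% and 9.44% in Ovol2 BT). Median intensities of 123, 126, 126 and 132 show the arrays on a similar scale, and the values were used without further normalization. Across genes, Pearson's r was 0.974 between the controls, 0.966 between the Ovol2 BT arrays and 0.934 to 0.963 between groups; genes are not independent replicates.

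The table holds 35557 probe sets. By the platform annotation used here, 21789 name 1 gene (19938 symbols), 1621 name several, and 12147 are not named. Of the probe sets naming 1 gene, 21698 matched the mouse reference table (GRCm38.p6, used for names only) by Entrez ID, with 0 symbols changed. Only probe sets naming 1 gene were tested, and for the 999 genes with several the one with the highest mean over the 4 arrays was used. Flg has no probe set of its own here and was not analysed.

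Values were tested as log2(intensity + 16), so fold changes are on that scale and understate changes of dim genes. The 25% of genes with the lowest mean level (4985) were left out, leaving 14953. A linear model with a group term was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, 2 residual and 6.95 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05; differences are Ovol2 BT minus control. Results were summarised and plotted with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. On simulated data with 200 changed genes of 14953 in 20 runs, with variances drawn from the fitted prior, this fit called 1.9% of genes changed 1.5-fold, 33.8% at 2-fold, 98.4% at 4-fold and 99.7% at 8-fold, and 5.5% of calls were false. A simulation run before it, which reused each gene's moderated variance and was replaced after its result was seen, called 18.5%, 78.5%, 100% and 100% at these sizes, with 7.9% of calls false. An absent call therefore says little about changes of 1.5-fold, and how much it says about 2-fold depends on the variances assumed. Both simulations drew independent noise for each gene and array. In the data, deviations of same-numbered arrays correlated at 0.41 across genes, so the simulated shares of false calls do not estimate that of the real calls.

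Gene lists for cell types of skin, epidermal layers, hair follicle, signalling and stress (42 lists, 40 with at least 5 tested genes) were fixed before the data were examined. So were the design, the gene naming rule and 18 of the alternatives. List shifts were tested with limma's camera (preset correlation 0.01, variance trend), which compares a list with all other genes, with adjustment over the 40 lists. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit. It can then lose a call even where the estimate is small.

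Genes named in the results follow a fixed rule. It takes the Ovol family, and the 12 largest increases and 12 largest decreases among called genes with the groups separated, leaving out predicted models and clones. It adds up to 4 members with the smallest p of each called or epidermal list, and a fixed set of epidermal and mesenchymal markers. Together 103 genes with a value were named this way, 35 of them called.

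The alternatives were another pseudocount (1 or 64), no filter or the lower 50% left out, quantile normalization or median centring, no or a robust variance trend, and the mean of a gene's probe sets. Further ones were the replicate number as a block, each array left out, a threshold of 0.10, strain-variable and histocompatibility genes left out, and the 2 other list tests. A further 2 were added after seeing the data: arrays centred on the median of the desmosome and adherens junction list (called cell junction genes in the results), and the adipocyte and brown adipocyte genes left out. A further 3 lists (brown adipocyte, which also enters that last alternative, hepatocyte and yolk sac, and simple epithelium and periderm) serve the closing section and were written after the first results were seen. Where an array was left out, 1 array stood for its group. The p of such a fit holds no spread between the arrays of that group. A call of a gene or list gained there is therefore no firmer evidence than the result with all arrays.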

Results

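Total RNA of mouse skin at E17.5 (embryonic day) was measured on 4 Affymetrix whole-transcript arrays, each holding RNA of 2 mice. The control group (2 arrays) carried the tetracycline-responsive Ovol2 transgene without a driver, or no transgene. The Ovol2 BT group (2 arrays) also carried the K5-tTA driver, which expresses the tetracycline transactivator from a keratin 5 promoter, active in the basal layer of the epidermis. Ovol2 encodes a zinc finger transcription factor of epithelia, and the series asks how differentiation of the epidermis changes when it is overexpressed there. Skin was used as a whole, so RNA of dermis, fat, vessels, nerve and underlying muscle was measured along with that of the epidermis. The median deposited intensity was 123 and 126 in control replicates 1 and 2, and 126 and 132 in Ovol2 BT replicates 1 and 2. The number of arrays limits the precision of each value below. The labels give the strain as CB6F1 for the controls and FVB/N for Ovol2 BT, while describing the mice as littermates, so strain and genotype cannot be told apart by the labels.

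Ovol2 itself was far higher in the Ovol2 BT arrays. Its deposited intensity was 360 and 161 in the controls and 4367 and 3893 in Ovol2 BT, a rise of 4.0 on the log2 scale (SE 0.33, 16.1-fold, limma adjusted p = 0.00309, 2 arrays per group). The related genes Ovol1 (log2 difference -0.34, SE 0.26, adjusted p = 0.660) and Ovol3 (0.17, SE 0.19, adjusted p = 0.759) did not pass the test. The position of the probes was not analysed here, so transcripts of the transgene and of the mouse's own Ovol2 were not told apart. Of 14953 genes tested, 144 passed an adjusted p of 0.05 in limma, 92 higher and 52 lower in Ovol2 BT. Of these, 87 of the higher and 47 of the lower genes differed at least 2-fold. With 1 array left out, which leaves a lone array that is assumed to vary like the others, more genes were called. Without control replicate 1 the count was 366 (221 higher, 145 lower), without control replicate 2 it was 212 (100 higher, 112 lower), and without Ovol2 BT replicate 2 it was 249 (137 higher, 112 lower). With each array centred on its cell junction genes, an alternative chosen after seeing the data that moved the median of all genes from -0.04 to 0.28, the split was 116 higher and 8 lower (93.5% higher against 63.9%). That centring also lowered the prior degrees of freedom of the variances from 6.95 to 4, which raises the p of a difference of the same size and SE. It moves the difference of every gene by the same amount, so a list's distance from all genes stays as it was, and camera's calls under it change only through the variances and are no test of the centring.

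Keratins of the basal layer were lower in Ovol2 BT skin. Krt15, a keratin of basal and hair follicle stem cells, fell by 2.29 on the log2 scale (SE 0.20, 4.88-fold, adjusted p = 0.00309). The basal keratin pair Krt5 and Krt14 fell by 1.1 (SE 0.16, 2.15-fold, adjusted p = 0.0148) and 1.24 (SE 0.20, adjusted p = 0.0225). Of the 20 tested genes of the basal keratinocyte list, these 3 were called, 7 were lower when adjusted over the list alone, and none was called higher. The list fell as a whole, with a median log2 difference of -0.44 (camera adjusted p = 4.17e-07, but adjusted p = 0.546 with an estimated correlation). Cd44, a hyaluronan receptor (-0.71, adjusted p = 0.233), and Trp63, the transcription factor that maintains basal cells (-0.35, SE 0.20, adjusted p = 0.581), did not pass the test. Without a variance trend the calls of Krt5 and Krt14 ended (adjusted p = 0.0525 and 0.0523). Under the junction centring that of Krt14 also ended (-0.91, SE 0.13, adjusted p = 0.0524), and the list's median was -0.12 against 0.28 for all genes.

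**Figure D1:**
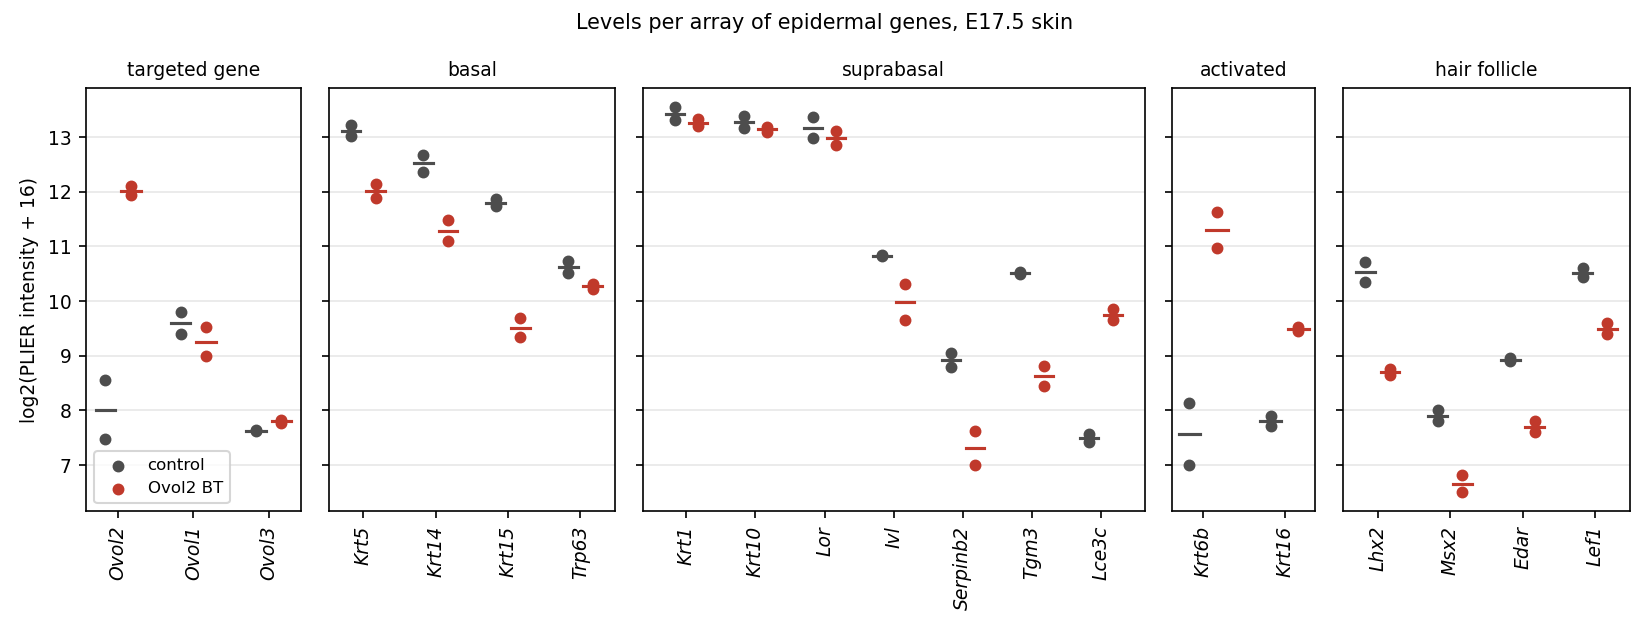
Level of each gene per array, as log2 of PLIER intensity plus 16, for the targeted gene family and for basal, suprabasal, activated and hair follicle genes; points are arrays (2 control, 2 Ovol2 BT) and short lines are group means. Both Ovol2 BT arrays lie below both controls for Krt5, Krt14 and Krt15, while the arrays of the groups overlap for Krt1, Krt10 and Lor.

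The abundant keratins of the suprabasal layers showed no detectable difference. Krt1 (-0.17, SE 0.14, adjusted p = 0.692), Krt10 (-0.13, SE 0.14, adjusted p = 0.754) and Lor, the main cornified envelope protein (-0.19, SE 0.17, adjusted p = 0.709), did not pass the test, and their values were 0.16, 0.19 and 0.14 with arrays centred on cell junction genes. Among late differentiation genes, the transglutaminase gene Tgm3 fell by 1.89 (SE 0.22, 3.71-fold, adjusted p = 0.00602) and the late cornified envelope gene Lce3c rose by 2.26 (SE 0.21, 4.78-fold, adjusted p = 0.00344). The granular and cornified envelope list, with 48 tested genes, was not called (median -0.24, camera adjusted p = 0.0505, and adjusted p = 0.790 with an estimated correlation). When adjusted over the list alone, 1 of its genes was higher and 3 were lower. Its envelope precursors Ivl (-0.85, SE 0.25, adjusted p = 0.245), Sprr1a (-1.09, adjusted p = 0.144) and Sprr3 (-1.26, adjusted p = 0.167) did not pass the test. In the spinous list 1 of 15 genes was called, the protease inhibitor gene Serpinb2, which fell by 1.61 (SE 0.25, adjusted p = 0.0213). When adjusted over the list alone, 1 gene was higher and 2 were lower. The keratin gene Krt77 (1.35, SE 0.41, adjusted p = 0.278) and the desmoglein gene Dsg1b (-1.09, adjusted p = 0.0589) were not called. The spinous list shifted down (median -0.26, camera adjusted p = 0.00503, but adjusted p = 0.562 with an estimated correlation). Its call ended without control replicate 1 (median -0.05, adjusted p = 0.619) and without Ovol2 BT replicate 2 (median -0.18, adjusted p = 0.145), and its median was -0.41 without control replicate 2. The granular list had a median of 0.01 without control replicate 1, -0.45 without control replicate 2 and -0.31 without Ovol2 BT replicate 1. It was called lower by camera with a pseudocount of 64 (adjusted p = 0.0498), without the filter (0.0310) and with the lower 50% left out (0.0198). The same held under quantile normalization (0.0132) and under median centring (0.0487). With arrays centred on cell junction genes the medians of the spinous and granular lists were 0.06 and 0.08, against 0.28 for all genes. There Tgm3 was at -1.57 (SE 0.23, adjusted p = 0.0524) and Serpinb2 at -1.28 (SE 0.30, adjusted p = 0.116), so their calls ended with differences somewhat smaller and fewer prior degrees of freedom. Differences moved with 1 array left out: Krt77 was at 2.13 without control replicate 1 and at 0.58 without control replicate 2. Sprr1a was at -1.48 and Sprr3 at -1.84 without control replicate 2, and Sprr3 at -1.46 without Ovol2 BT replicate 1. Ivl was at -1.18 and Dsg1b at -1.22 without Ovol2 BT replicate 2. Without control replicate 1 Sprr1a and Sprr3 were at -0.70 and -0.69, and without Ovol2 BT replicate 1 Ivl was at -0.52. Dsg1b was called by limma with the lower 50% left out (adjusted p = 0.0317) and under median centring (0.0423).

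Genes of hair follicle formation were lower in Ovol2 BT. Lhx2, a transcription factor of hair follicle progenitors, fell by 1.83 (SE 0.22, 3.55-fold, adjusted p = 0.00729). The homeobox gene Msx2 fell by 1.24 (SE 0.19, adjusted p = 0.0190), and Edar, the ectodysplasin receptor needed for hair placodes, fell by 1.22 (SE 0.21, adjusted p = 0.0299). Lef1, a transcriptional partner of beta-catenin, was at -1.03 (SE 0.20, adjusted p = 0.0651). These 3 called genes were the only calls among the 31 tested genes of the placode and matrix list, with 10 lower when adjusted over the list alone, and the list fell (median -0.41, camera adjusted p = 7.83e-07, but adjusted p = 0.548 with an estimated correlation). In the Wnt list 1 of 31 genes was called, the Wnt inhibitor gene Dkk1, which fell by 1.57 (SE 0.22, adjusted p = 0.0137). The ligand genes Wnt4 (-1.09, adjusted p = 0.0502) and Wnt16 (-0.78, adjusted p = 0.244) did not pass. The Wnt list fell, with 3 genes lower when adjusted over the list alone (median -0.25, camera adjusted p = 0.000821, but adjusted p = 0.546 with an estimated correlation). The dermal papilla list shifted down with 0 of 18 genes called by limma and 8 lower at an unadjusted p under 0.05 (median -0.35, camera adjusted p = 0.00152, but adjusted p = 0.546 with an estimated correlation). It includes Alx4 (-0.77), Sox2 (-0.71), Prdm1 (-0.70) and Cxcr4 (-0.70). The hair shaft and inner root sheath list was not called (camera adjusted p = 0.983): its median was 0.10 while its mean was -0.18 and the test's direction was down, with only Msx2 called of 26 genes, and its inner sheath keratins Krt25 (-1.47, adjusted p = 0.272), Krt28 (-1.19, adjusted p = 0.171) and the companion layer keratin Krt75 (-1.14, adjusted p = 0.143) not called. Of its 26 genes 16 had higher values, and when adjusted over the list alone 2 were higher and 4 were lower. Without control replicate 1, Krt25 was at -2.30, Krt28 at -1.64, Krt75 at -1.60 and Wnt16 at -1.0, while the keratins were at -0.64, -0.74 and -0.69 without control replicate 2. The size of these keratin differences thus rests on which control array is used. Lef1 was called by limma with the lower 50% left out (adjusted p = 0.0296) and was at -1.13 without Ovol2 BT replicate 1. Wnt4 was called with the lower 50% left out (0.0318), under median centring (0.0411) and without a variance trend (0.0426). Its difference was -1.16 without control replicate 2. Edar lost its call without Ovol2 BT replicate 2 (adjusted p = 0.0553) and under quantile normalization (adjusted p = 0.0531). With arrays centred on cell junction genes the calls of Lhx2 (-1.50, SE 0.24, adjusted p = 0.0605), Msx2 (-0.92, SE 0.20, adjusted p = 0.112), Edar (-0.90, SE 0.19, adjusted p = 0.104) and Dkk1 (-1.25, SE 0.20, adjusted p = 0.0605) ended, with differences smaller by the shift of the centring and fewer prior degrees of freedom. The medians of the placode, Wnt and dermal papilla lists were then -0.08, 0.07 and -0.03, against 0.28 for all genes.

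Pigment cell genes shifted down as a list. Tyr, which encodes tyrosinase, fell by 1.15 (SE 0.20, adjusted p = 0.0327) and was the only call among 13 genes, with 2 lower when adjusted over the list alone. Dct (-0.88, adjusted p = 0.136), Mlana (-0.71, adjusted p = 0.369) and Slc45a2 (-0.54, adjusted p = 0.364) were not called. The list's median was -0.38 (camera adjusted p = 0.000627, but adjusted p = 0.546 with an estimated correlation). Tyr also varies between inbred strains and lost its call without a variance trend (adjusted p = 0.0808) and with arrays centred on cell junction genes (-0.83, SE 0.27, adjusted p = 0.140), where the list's median was -0.06. The list's call ended without Ovol2 BT replicate 2, and Mlana was at -1.08 without Ovol2 BT replicate 1 and at -0.33 without Ovol2 BT replicate 2.

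Cell cycle genes were lower together, by small amounts. In the S phase list 27 of 28 genes had lower values in Ovol2 BT, with a median log2 difference of -0.51 (camera adjusted p = 2.39e-09, but adjusted p = 0.477 with an estimated correlation). Tyms, which encodes thymidylate synthase, was at -0.73 (SE 0.20, adjusted p = 0.213), the replicative helicase gene Mcm6 at -0.73 (SE 0.22, adjusted p = 0.264), Gins1 at -0.71 (SE 0.17, adjusted p = 0.132) and the chromatin assembly gene Chaf1b at -0.60 (SE 0.21, adjusted p = 0.364). All 29 genes of the mitosis list had lower values, among them Bub1b (-0.70), Ttk (-0.67), Kif2c (-0.63) and Aurka (-0.52), with a median of -0.33 (camera adjusted p = 1.40e-05, but adjusted p = 0.546 with an estimated correlation). No single gene of either list was called by limma, over all genes or when adjusted over the list alone; 16 and 7 genes were lower at an unadjusted p under 0.05. Myc, a transcription factor of growth, was at -0.44 (SE 0.22, adjusted p = 0.548). Without control replicate 2 the mitosis list was not called (median -0.27), and without Ovol2 BT replicate 2 Gins1 was at -0.88. With arrays centred on cell junction genes the medians of the S phase and mitosis lists were -0.19 and -0.01, against 0.28 for all genes.

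Adipocyte genes were higher in Ovol2 BT skin, with the largest list median of the 40 lists tested. All 22 tested genes of the list had higher values and 14 were called, 20 when adjusted over the list alone. The median log2 difference was 2.08 (camera adjusted p = 1.04e-36, but adjusted p = 0.477 with an estimated correlation). The lipid droplet gene Cidea rose by 3.14 (SE 0.29, 8.81-fold, adjusted p = 0.00315) and Plin4, another lipid droplet gene, by 2.32 (SE 0.26, adjusted p = 0.00513). Pck1, an enzyme of glyceroneogenesis, rose by 3.09 (SE 0.33, adjusted p = 0.00478), and Ucp1, the uncoupling protein of brown fat, by 2.31 (SE 0.25, adjusted p = 0.00478). Pparg, the nuclear receptor that directs fat cell formation, was at 0.95 (SE 0.23, adjusted p = 0.144), and at 1.22 without Ovol2 BT replicate 1. The mean log2 level of the list was 9.05 and 8.46 in the controls and 10.70 and 10.69 in Ovol2 BT. The fibroblast and matrix list stood at 11.25, 11.26, 11.30 and 11.32 in the same order of arrays, and was not called (median 0.03, camera adjusted p = 0.279).

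**Figure D2:**
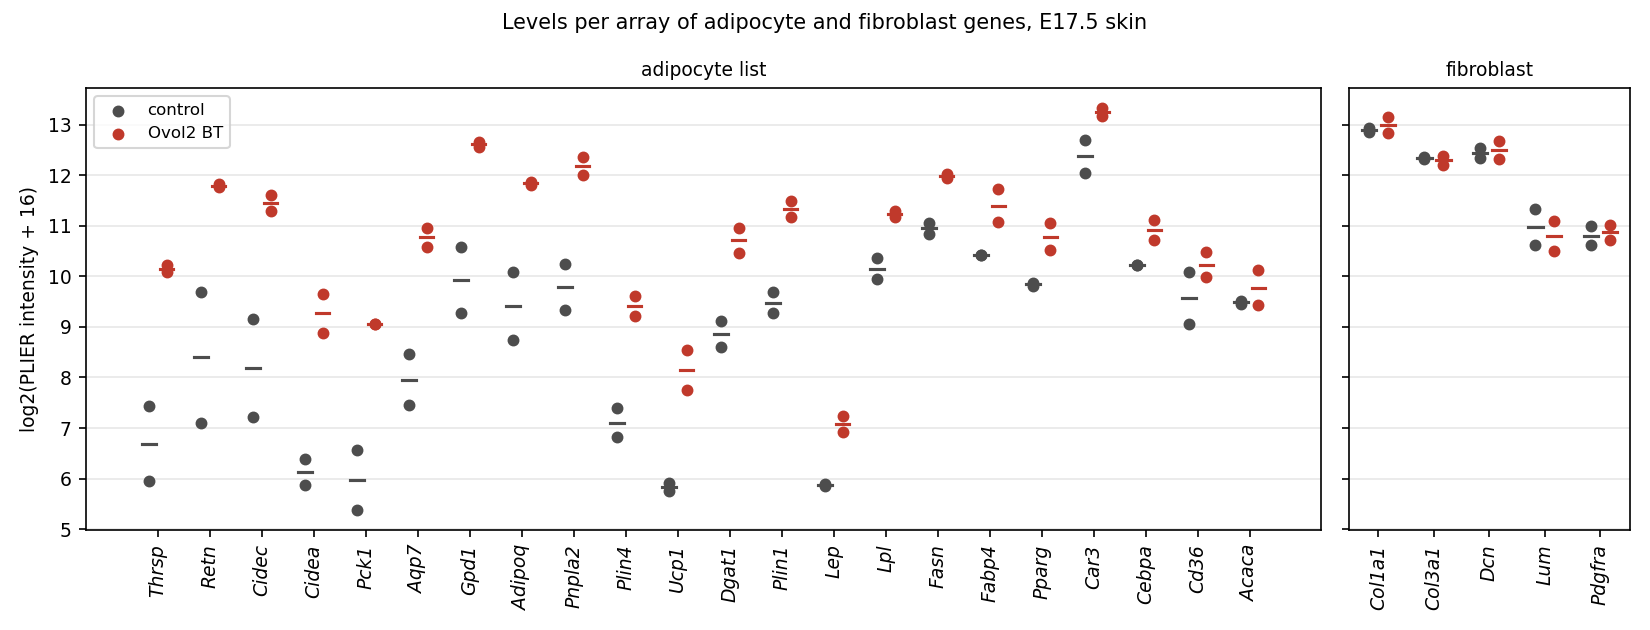
Level of each gene per array, as log2 of PLIER intensity plus 16, for the 22 tested genes of the adipocyte list and 5 fibroblast genes; points are arrays (2 control, 2 Ovol2 BT) and short lines are group means. The median log2 difference of the adipocyte list is 2.08 and that of the whole fibroblast and matrix list 0.03.

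Genes of the adipocyte list were also among the largest increases, in arrays whose adipocyte list means were 9.05 and 8.46 (control) and 10.70 and 10.69 (Ovol2 BT). After Ovol2, the largest rises among called genes were those of the amino acid transporter gene Slc36a2 (3.86, SE 0.49, adjusted p = 0.00893) and of Krt6b, a keratin of activated keratinocytes (3.73, SE 0.37, 13.3-fold, adjusted p = 0.00457). Next were Thrsp, a regulator of lipid synthesis (3.46), the lipid droplet gene Cidec (3.28), the cytochrome oxidase subunit gene Cox7a1 (3.14), Cidea, Adhfe1 (3.12), Pck1, the carboxylesterase gene Ces1d (2.98), the glycerol channel gene Aqp7 (2.81) and the potassium channel gene Kcnk3 (2.81). Of the 12 largest increases, 5 belong to the adipocyte list (Thrsp, Cidec, Cidea, Pck1 and Aqp7). Leaving out the adipocyte and brown adipocyte lists, an alternative chosen after seeing the data, left 73 genes higher and 52 lower. The adipocyte list held 14 and the brown adipocyte list 3 of the genes called higher with all genes tested. Cox7a1, Slc36a2 and Kcnk3, which brown fat also expresses, are in neither list and stayed among the tested genes. The remaining genes were not checked for further fat genes, so the 73 cannot be taken as increases outside fat. Cidec lost its call with arrays centred on cell junction genes although its difference was larger (3.60, SE 0.54, adjusted p = 0.0539).

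The largest decreases included serpin, water channel and keratin genes. The serpin genes Serpinb3c and Serpinb10 fell by 2.74 (SE 0.34, adjusted p = 0.00758) and 2.49 (SE 0.22, adjusted p = 0.00309), and Ptprz1, a receptor tyrosine phosphatase gene, by 2.45 (SE 0.17, adjusted p = 0.00154). Aqp3, the water and glycerol channel of basal keratinocytes, fell by 2.39 (SE 0.23, 5.23-fold, adjusted p = 0.00401). Gadl1 fell by 2.38, and lower values were also called for Krt13, a keratin of non-cornified stratified epithelia (-2.10), Bnc1, which encodes the basal cell factor basonuclin 1 (-2.07), and Adh6b (-2.02). Krt15, Tgm3 and Lhx2, described above, complete the 12 together with Alb, the albumin gene, which fell by 2.63 (SE 0.45, adjusted p = 0.0327). Alb intensities were 305 and 865 in the controls and 46.1 and 104 in Ovol2 BT. A second, dimmer Adh6b probe set differed by -0.06, and the mean of both gave -1.04. Alb and Krt13 lost their calls without a variance trend (adjusted p = 0.0561 and 0.0551), and Krt13 also under quantile normalization (0.0579). Under the junction centring, with fewer prior degrees of freedom, the calls of Alb (-2.30, SE 0.59, adjusted p = 0.123), Krt13 (-1.78, SE 0.37, adjusted p = 0.104), Serpinb3c (-2.42, SE 0.44, adjusted p = 0.0870) and Adh6b (-1.70, SE 0.26, adjusted p = 0.0582) ended while most of each difference stayed.

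Genes of epithelial-mesenchymal transition did not shift as a list in whole skin, where RNA of the dermis may hide a change within the epidermis. Of 25 genes, 0 were called by limma, 2 were lower at an unadjusted p under 0.05, and the median was -0.08 (camera adjusted p = 0.258). The mesenchymal transcription factor gene Zeb1 was at 0.19 (SE 0.24, adjusted p = 0.802) and Vim, which encodes vimentin, at -0.07 (SE 0.14, adjusted p = 0.873). Cdh1, which encodes E-cadherin, was at -0.17 (SE 0.18, adjusted p = 0.752). Snai1 (-0.37), Tgfb2 (-0.54) and Tgfb3 (-0.39) were not called either, nor was Lef1 (-1.03), the only gene that was lower when adjusted over the list alone. The list's median was -0.15 without control replicate 1 and -0.14 without Ovol2 BT replicate 1, and 0.25 with arrays centred on cell junction genes, against 0.28 for all genes. The signs of Vim and Cdh1 turned with arrays centred on cell junction genes (0.25 and 0.15), that of Vim also without control replicate 1 (0.04), and that of Zeb1 without Ovol2 BT replicate 2 (-0.09).

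Cell junction genes, epidermal transcription factors and TGF-beta and BMP signalling genes shifted down slightly. In the desmosome and adherens junction list 0 of 19 genes were called by limma (1 higher and 3 lower at an unadjusted p under 0.05), with Dsc3 at -0.98 (adjusted p = 0.114), Dsg3 at -0.59, Pkp1 at -0.53 and Dsc2 at 0.49. Its median was -0.24 (camera adjusted p = 0.00510, but adjusted p = 0.546 with an estimated correlation). In the epidermal transcription factor list 0 of 39 genes were called (3 higher and 9 lower at an unadjusted p under 0.05), with Irx4 at -1.15 (adjusted p = 0.0580), Dlx5 at -1.23 (adjusted p = 0.123) and Grhl2 at -0.95 (adjusted p = 0.0830). Pparg, given above with the adipocyte genes, is also in this list and had a higher value (0.95, limma adjusted p = 0.144). That list's median was -0.31 (camera adjusted p = 0.00161, but adjusted p = 0.562 with an estimated correlation). The TGF-beta and BMP list had a median of -0.21 (camera adjusted p = 0.0454, but adjusted p = 0.546 with an estimated correlation), with 0 of 26 genes called and 2 lower at an unadjusted p under 0.05; Bmp2 was at -0.64 and Bambi at -0.57. Without control replicate 1 and without Ovol2 BT replicate 2 the calls of the junction list (medians -0.12 and -0.24, adjusted p = 0.202 and 0.101) and the transcription factor list (-0.22 and -0.21, 0.146 and 0.240) ended. The TGF-beta and BMP list was not called without any 1 of the 4 arrays (adjusted p from 0.102 to 0.218, with medians of -0.14 without control replicate 2 and -0.10 without Ovol2 BT replicate 1), nor with the lower 50% left out (0.102), under quantile normalization (0.0869) or, at the threshold, median centring. With arrays centred on cell junction genes the medians of the 3 lists were 0.08, 0.01 and 0.11, against 0.28 for all genes. Dsc3 was at -1.16 without control replicate 1 and at -1.15 without Ovol2 BT replicate 2. Dlx5 was at -1.65 without control replicate 2, against -0.81 without control replicate 1. Irx4 was at -1.16 without control replicate 1 and at -1.36 without Ovol2 BT replicate 1. It was called by limma with the lower 50% left out (adjusted p = 0.0261) and under median centring (0.0430).

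Skeletal muscle, endothelial, histocompatibility and interferon response lists shifted up slightly. In the muscle list 35 of 37 genes had higher values, with a median of 0.30 (camera adjusted p = 7.83e-07, but adjusted p = 0.562 with an estimated correlation), and its genes include Myh2 (0.57), Cacng1 (0.52), Atp2a1 (0.42) and Des (0.41). Its mean level was 9.83 and 9.84 in the controls and 9.95 and 10.29 in Ovol2 BT. The endothelial list had a median of 0.14 (camera adjusted p = 0.0423, but adjusted p = 0.560 with an estimated correlation), with Cldn5 at 0.50 and Flt1 at 0.42. The histocompatibility list, whose genes differ between inbred strains, had a median of 0.19 (camera adjusted p = 0.00461, but adjusted p = 0.546 with an estimated correlation), with H2-M3 at 0.56 and H2-Eb1 at 0.47. No gene of these 3 lists was called by limma, and 7, 0 and 2 were higher at an unadjusted p under 0.05. The interferon list had a median of 0.24 (camera adjusted p = 0.00598, but adjusted p = 0.625 with an estimated correlation), with 1 of 21 genes called: Ifi27, which rose by 1.30 (SE 0.22, adjusted p = 0.0297). When adjusted over that list alone, 2 genes were higher. The interferon-induced genes Cxcl10 (-0.62) and Ifit2 (-0.37) had lower values and were not called with all arrays. Cxcl10 was at -1.04 without control replicate 2, against -0.21 without control replicate 1. Calls ended without Ovol2 BT replicate 2 for the muscle (median 0.13, adjusted p = 0.101), endothelial (0.205) and interferon lists (median -0.03, adjusted p = 0.637). Without control replicate 2 they ended for the endothelial (0.191), histocompatibility (0.169) and interferon lists (0.321) and for Ifi27 (adjusted p = 0.0581), and without control replicate 1 for the endothelial list (0.144), whose call also ended without the filter (0.0948). The muscle median was 0.49 without Ovol2 BT replicate 1, and the interferon median was 0.15 with a pseudocount of 64 and 0.07 without control replicate 2. Under the junction centring the medians of the muscle, endothelial, histocompatibility and interferon lists were 0.63, 0.47, 0.51 and 0.56, against 0.28 for all genes, and the interferon call ended (adjusted p = 0.0949) through the variances.

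**Figure D3:**
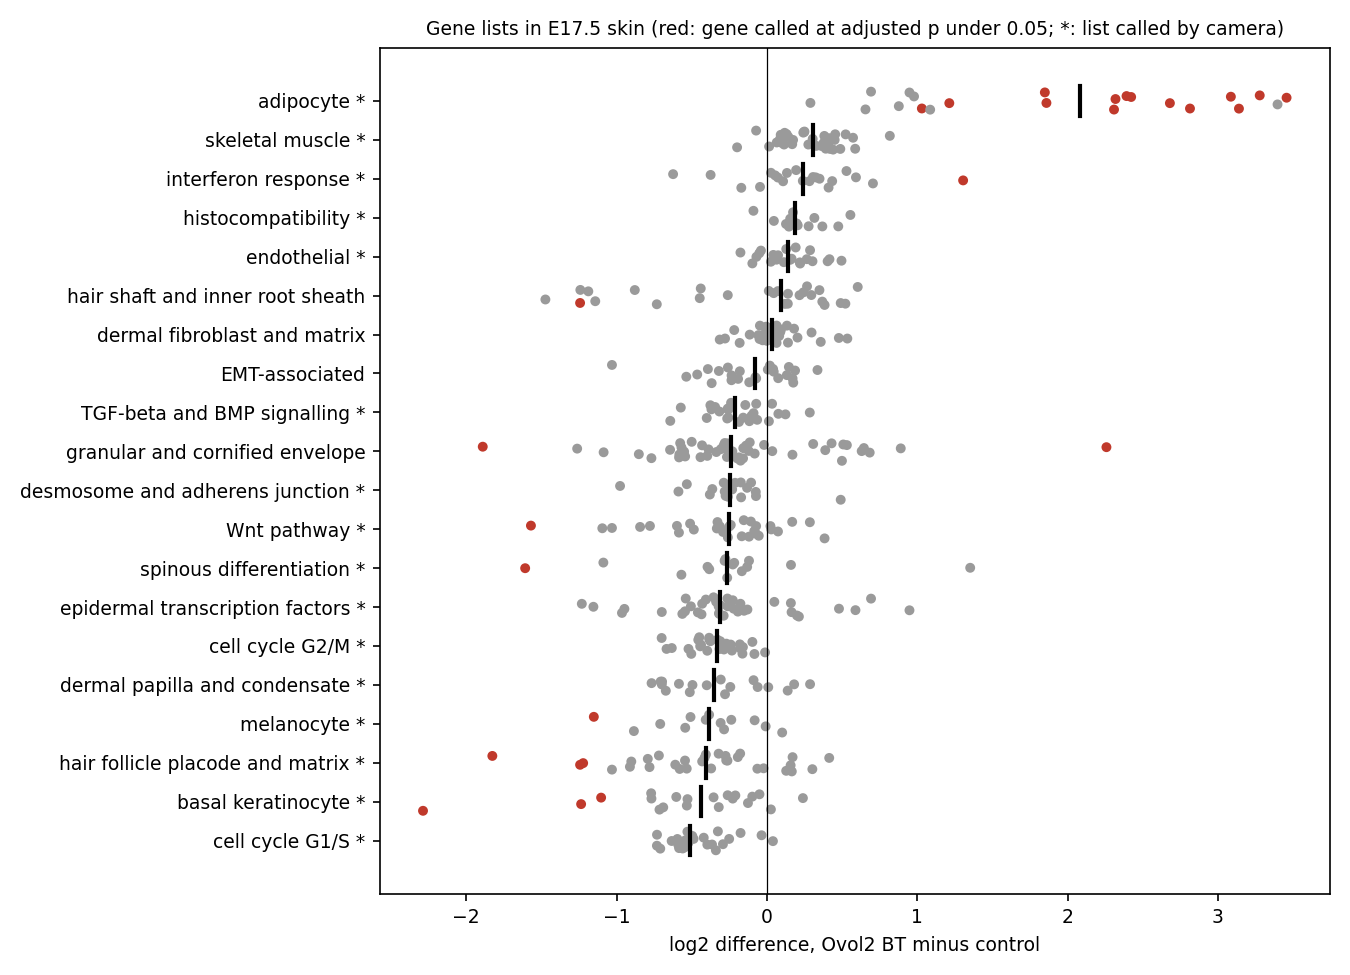
Log2 difference, Ovol2 BT minus control, of each tested gene (points) in the 16 lists called by camera and 4 further lists, with the list median as a black bar, genes called at an adjusted p under 0.05 in red and called lists marked by an asterisk. The adipocyte list has a median of 2.08, and the medians of the other called lists lie between -0.51 and 0.30; with arrays centred on cell junction genes those of the spinous, junction, Wnt, transcription factor and TGF-beta and BMP lists lie above 0, against 0.28 for all genes.

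Of the 40 lists tested, 16 were called with camera's preset correlation, 5 up and 11 down. With a correlation estimated from these 4 arrays 0 were called (2 at an unadjusted p under 0.05), and by fry 0 (8 at an unadjusted p under 0.05). The estimates for the S phase (0.0042), TGF-beta and BMP (-0.037) and dermal papilla (-0.042) lists were not above the preset 0.01. For the other called lists they ranged from 0.041 (pigment cells) to 0.47 (interferon). With 2 residual degrees of freedom the calls ended in either case, so their loss does not by itself show correlation between genes. The adipocyte, basal keratinocyte, S phase, hair follicle placode, Wnt and dermal papilla lists kept their calls whichever array was left out, and the other 10 lost them without at least 1 array.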

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

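Most results kept their direction. Under pseudocounts of 1 and 64, no filter, the lower 50% left out, quantile normalization, median centring, no or a robust variance trend and the mean of probe sets, 111 to 196 genes were called against 144, and 16 to 19 lists against 16. Of the 35 named called genes, 5 lost their call without a variance trend, 2 under quantile normalization and 0 under the others of these (26 tested with the lower 50% left out). An adjusted p of 0.10 called 215 genes, and 143 were called without the strain-variable and histocompatibility lists. These lists have 12 and 14 tested genes with 1 and 0 calls, so the count could hardly move and does not bear on strain. With each array left out, which leaves a group with 1 array assumed to vary like the others, 209 to 366 genes were called (100 to 221 higher, 72 to 145 lower), 440 to 820 passed 1.5-fold at an unadjusted p under 0.01 (497 with all arrays), and 9 to 19 lists were called; Ovol2 stayed between 3.46 and 4.55. With the replicate number as a block, 652 genes were called (315 higher, 337 lower), including all 144, and 872 passed 1.5-fold; no named call was lost, 30 were gained, and 18 lists were called, the granular (adjusted p = 0.0230) and leukocyte (0.0461) lists in addition. Deviations of same-numbered arrays from their group means correlated at 0.41 across genes. With 2 pairs and no label on pairing, the numbers were not taken to pair the arrays. The numbers do go with sex-linked genes: Eif2s3y, Kdm5d and Uty were higher, and Xist lower, in replicate 1 of both groups. Camera with an estimated correlation and fry called 0 lists each. With arrays centred on cell junction genes, chosen after seeing the data, 124 genes were called, 94 of them shared with the 144; 8 were lower, 13 of the 35 named calls were lost and 1106 genes passed 1.5-fold. Leaving out the adipocyte and brown adipocyte lists, also added later, gave 125 calls. Directions turned for the hair shaft list without the filter (test up, median 0.13), without those fat lists (test up, 0.096) and without Ovol2 BT replicate 2 (test up, 0.11; 0.048 to 0.11 over the arrays left out, and called lower without control replicate 1, adjusted p = 0.0204), whose median was -0.35 with the lower 50% left out. The test of the keratinocyte activation list turned down without the filter (0.0048), under quantile normalization (-0.004), median centring (0.087) and junction centring (0.37), and without control replicate 2 or Ovol2 BT replicate 1 (range -0.067 to 0.097). It also turned down for the cholesterol list without the filter (-0.014) and without control replicate 2 (range -0.14 to 0.13), and for the erythroid list without Ovol2 BT replicate 1 (range -0.038 to 0.29). The p53 list turned down without the filter (-0.047), by fry (-0.047), under junction centring (0.28) and without Ovol2 BT replicate 2 (range -0.082 to -0.019), the oxidative stress list down with the lower 50% left out (-0.31), under junction centring (0.21) and without control replicate 2 (range -0.16 to 0.051), and the hypoxia list down without control replicate 2 (range -0.12 to 0.29). The Notch list turned up with the lower 50% left out (-0.11), under quantile normalization (-0.038), junction centring (0.20) and without control replicate 1 or Ovol2 BT replicate 2 (range -0.23 to 0.018), the strain-variable list up with the lower 50% left out (-0.051) and without Ovol2 BT replicate 1 (range -0.28 to 0.094), and the AP-1 list up without control replicate 1 or Ovol2 BT replicate 2 (range -0.26 to 0.063); the values given are medians, whose sign can differ from the test's direction. The tight junction median turned without control replicate 2 (range -0.055 to 0.23) while its test stayed up. The barrier lipid list turned up without control replicate 1 (range -0.515 to 0.045). Signs also turned for the granular list (0.0078; range -0.45 to 0.0078) and Vim (0.036; range -0.18 to 0.036) without control replicate 1, and for Zeb1 (-0.0855; range -0.0855 to 0.46) and Zic1 (0.0068; range -0.11 to 0.0068) without Ovol2 BT replicate 2, for Krt18 without control replicate 1 and Ovol2 BT replicate 2 (range -0.676 to 0.23), and for Zic1 under quantile normalization (0.041). Under the junction centring they turned for Cdh1 (0.15), Krt1 (0.16), Krt10 (0.19), Lor (0.14), Vim (0.25), Krt18 (0.10), Nnt (0.13) and Zic1 (0.27), a shift built into that scaling; none of these was called in either setting. The causes of the other changes were not tested, except that fewer arrays or genes enter some fits. The deposited values carry no background estimate, so the dimmest gene that can be measured is not known.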

Other observations

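The called genes in this paragraph were chosen after their values were seen, from lists fixed before the data were examined, and the related keratin genes Krt6a, Krt17 and Krt18 were added beside them. Among keratinocyte activation genes, Krt6b and its common partner Krt16 (1.69, SE 0.21, adjusted p = 0.00758) rose, while the gap junction gene Gjb2 (-1.26, SE 0.23, adjusted p = 0.0431) and Serpinb3c fell. Genes of that list went both ways, and the list was not called (27 genes, median 0.05, camera adjusted p = 0.976). Krt6a (1.74, SE 0.45, adjusted p = 0.171) and Krt17 (0.17, SE 0.16, adjusted p = 0.729) did not pass the test. Krt6a was at 2.03 without control replicate 1 and at 1.46 without control replicate 2. It was at 2.54 without Ovol2 BT replicate 2 and at 0.95 without Ovol2 BT replicate 1. Gjb2 lost its call without control replicate 1 (-0.99, adjusted p = 0.114), without the filter (0.0617), without a variance trend (0.0557) and with arrays centred on cell junction genes (-0.94, SE 0.19, adjusted p = 0.10). Krt8, a keratin of simple epithelia and Merkel cells, rose by 2.19 (SE 0.24, adjusted p = 0.00497), with intensities of 448 and 351 in the controls and 2181 and 1597 in Ovol2 BT, while its usual partner Krt18 was at -0.22 (SE 0.32, adjusted p = 0.820), and at 0.09 without control replicate 1 and 0.23 without Ovol2 BT replicate 2. The tight junction gene Cldn6 rose by 2.03 (SE 0.21, adjusted p = 0.00469), the only call among 17 tight junction genes (median 0.09, camera adjusted p = 0.156; median 0.23 without control replicate 1 and -0.05 without control replicate 2). The antioxidant gene Gpx2 rose by 1.30 (SE 0.17, adjusted p = 0.01). In the barrier lipid list the desaturase gene Scd1, which adipocytes also express, rose by 2.23 (SE 0.26, adjusted p = 0.00602) and the ceramide synthesis gene Sptlc3 fell by 1.25 (SE 0.23, adjusted p = 0.0426). The call of Sptlc3 ended without control replicate 1 (-1.05, adjusted p = 0.0524), without Ovol2 BT replicate 1 (-1.14, 0.0763), without the filter (0.0503), under quantile normalization (0.0684) and with arrays centred on cell junction genes (-0.93, SE 0.21, 0.114). The barrier lipid list was not called (33 genes, median -0.22, camera adjusted p = 0.152). Its median was -0.51 without control replicate 2 and turned up to 0.045 without control replicate 1.

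Of the 24 lists that were not called, the leukocyte and macrophage list had a median of 0.05 (camera adjusted p = 0.0727), the erythroid list 0.04 (0.258), the Schwann cell and nerve list -0.16 (0.364) and the cholesterol synthesis list -0.01 (0.812). The leukocyte list was called higher without control replicate 2 (median 0.15, adjusted p = 0.0498), without Ovol2 BT replicate 1 (0.20, 0.0382), under quantile normalization (0.12, 0.0380) and with the lower 50% left out (0.06, 0.0158), and the erythroid list without Ovol2 BT replicate 2 (0.29, 0.0203). The lists of Langerhans and mast cells (median 0.11, adjusted p = 0.156), mural and smooth muscle cells (0.15, 0.156), axon guidance (-0.16, 0.156), integrins and motility (-0.16, 0.184), hypoxia and glycolysis (0.07, 0.156), AP-1 and immediate early genes (-0.10, 0.274), heat shock (-0.09, 0.350), Notch (-0.12, 0.834), housekeeping (-0.11, 0.269) and strain-variable genes (-0.05, 0.812) were not called either. For the lists of Merkel and sebaceous cells (median -0.11, 0.330), oxidative stress (-0.12, 0.674), p53 (-0.05, 0.949) and cholesterol synthesis the test's direction was up while the median was below 0. The hypoxia list was called higher without control replicate 1 (0.29, 0.0150), with the lower 50% left out (0.0475) and under quantile normalization (0.0261), and its test turned down without control replicate 2 (-0.12, 0.862). The AP-1 list was called lower without control replicate 2 (-0.26, 0.0375) and without Ovol2 BT replicate 1 (-0.19, 0.0186), the axon guidance list lower without Ovol2 BT replicate 1 (-0.27, 0.0203), the lists of Langerhans and mast cells (0.05) and Merkel and sebaceous cells (median -0.12, test up) higher without control replicate 2 (both 0.0498), and the mural list higher under quantile normalization (0.0454). Among genes of liver and yolk sac, in a list written after some of its values were seen, Cubn fell by 1.70 (SE 0.14, adjusted p = 0.00309), the only call of 11 (median -0.87). Alb (-2.63), called lower above, is not in that list, so the list's median and count of calls do not stand for liver genes in general. Apob intensities were 739 and 93.3 in the controls and 86.3 and 88.9 in Ovol2 BT, and those of Apoa1 were 2715 and 484 against 483 and 349. The list of simple epithelium and periderm, also written after some values were seen, had a median of -0.39 over 12 genes, with Cldn6 called higher and Krt13 lower. Krt8 (2.19), called higher above, is not in it, so this median does not stand for simple epithelium genes in general. All labels give the sex as female. The Y-linked gene Eif2s3y had intensities of 149 and 20 in control replicates 1 and 2 and 164 and 1.3 in Ovol2 BT replicates 1 and 2. Kdm5d (122, 23.6, 134 and 10.5) and Uty (55.5, 6.7, 69.5 and 3.2) had the same order, and Xist had 1016, 2839, 448 and 1875. Sry (390, 348, 440 and 376) and the dim Zfy1 (16, 0, 6.7 and 1.2) were also higher in replicate 1 of both groups, Sry by little. The probe sets of Usp9y and Zfy2 were lower in replicate 1 of both groups. Probe sets naming several genes (1005 tested) or not named here (5566 tested) gave 0 calls in limma, with 63 and 385 at an unadjusted p under 0.05.

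In the paragraphs that follow, the brown fat and strain tests were written before their results were seen, and the other tests after; the basal keratins were first tested together, which decided nothing, and then gene by gene. The rise of adipocyte genes was not shared by all tissue below the epidermis: the fibroblast and matrix list had a median of 0.031 (95% bootstrap interval -0.005 to 0.082, 31 genes), far below the adipocyte list's 2.084. The skeletal muscle list, also of tissue below the epidermis, had a median of 0.30. The bootstrap intervals of lists given here resample genes, so they leave out the variation between arrays. Brown fat carried along with the skin cannot be told apart from a rise within the skin's own fat, since 19 brown fat genes had a median of 0.477 (0.205 to 0.859), with Cox8b (2.01), Pdk4 (1.46) and Ebf2 (1.33) called and Zic1 (-0.05) and Prdm16 (0.28) not; that list left out brown fat genes already seen to rise, among them Ucp1 (2.31), Cidea (3.14), Cox7a1 (3.14), Slc36a2 (3.86) and Kcnk3 (2.81), so its median does not stand for brown fat genes in general. Of the 75 called-higher genes outside the fat lists, 82.7% were also higher in the control array with more adipocyte RNA. In 95% of 10000 random sets of uncalled genes matched on level, the share was 44.0% to 65.3%. The 75 still hold such genes as Cox7a1, Slc36a2 and Kcnk3, which brown fat also expresses, so a high share could follow from the choice of genes. The share also rests on the pair of control arrays alone, and the random sets hold genes that need not vary together. A varying fat content stays a candidate explanation for part of the increases, which this share cannot decide. The genotype itself, which the design names, stays open as well and was not tested apart from these.

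The fall of basal keratins could come from a smaller share of epidermis, which was examined by centring each array on its cell junction genes. The centring moves every gene's difference by the same amount. Its rule was written after these falls were seen, so most of a large fall was bound to stay. Krt5 stayed at -0.779 (95% interval -1.001 to -0.557, limma adjusted p = 0.0324) and Krt15 at -1.964 (-2.336 to -1.591, adjusted p = 0.0206). Both thus fell further than the median of the junction genes, as far as these track the share of epidermis, which by itself decides no cause. Krt14 went from -1.24 (SE 0.20) to -0.912 (SE 0.13, interval -1.234 to -0.59, limma adjusted p = 0.0524). Its call ended as prior degrees of freedom fell from 6.95 to 4. Krt14 kept 73.8% of its difference and Krt5 kept 70.6%, so these values do not set Krt14 apart from Krt5. For the basal list as a whole the share of epidermis stays open, since the list's median lay 0.198 below that of the junction list (difference -0.198, bootstrap interval over genes -0.473 to 0.041). A lower basal program under Ovol2 is a hypothesis that these values leave open for Krt5, Krt14 and Krt15, and it was not tested.

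The strain labels differ between the groups, so that strain background may contribute to any call. Nnt, of which the C57BL/6J parent of CB6F1 can carry a deletion, was at -0.193 in the values as deposited (95% interval -0.657 to 0.27). This interval lies below the rise of 0.5 or more set in advance for such a difference, while its lower limit passes the -0.5 set for no difference. With arrays centred on cell junction genes Nnt was at 0.13 (-0.36 to 0.62), an interval that includes that rise. The position of the probes was not analysed, so a strain difference need not show as such a rise. The test therefore decides nothing on strain. A single gene does not stand for other strain differences, and since the strain labels follow the groups on all arrays, strain cannot be told apart from genotype here.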
